A study of Mus musculus with 18 samples.

How the data were processed

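RNA was measured in 6 samples of MC3T3-E1 subclone 4 cells on day 3 in osteogenic medium, 3 given 0.25% DMSO and 3 given 2.5 µM EPZ6438, and the histone marks H3K27me3 and H3K4me3 were measured by chromatin immunoprecipitation with input controls. Groups and replicate numbers were taken from the labels.

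The authors deposited expression as RPKM, reads per kilobase of gene length and per 1000000 reads in genes, per the file headers, for 43346 genes, with gene positions and no strand. For each mark and arm the authors deposited 1 list of other values, peak starts and ends with no height or score, which per the file names came from merged samples called against the input of the same arm. The tools bcl2fastq, FastQC, STAR 2.6.1c, Subread, MACS2, Picard, HOMER and DiffBind and the genome build mm10 are named per the submitters' processing notes, without roles. Caller thresholds, the annotation release, the strand setting of counting and the way samples were merged are not given in the sources used here.

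RPKM times length (plus 1 base) over 1000 summed to 1000000 per library, and divided by its smallest step gave whole reads for 100% of values above 0 (tolerance 0.001). This gave library totals of 18807156 to 25365513 reads. A floor of 3 reads corresponds to 0.118 to 0.160 CPM. Reads carry no molecular identifiers, so such floors and all binomial intervals cover counting error only. The 37 genes of chrMT were at 0 in every library and were left out of gene counts by position. Symbols were those of the table; 42462 of its IDs are in the reference names, and all 918 entries of 36 gene lists were found.

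Because the values are RPKM, the planned count test was not used. Genes with at least 10 recovered reads in at least 3 libraries were tested with limma 3.58.1 (trend, empirical Bayes, two-sided) on log2(RPKM + 0.1) in R 4.3.3, with no block, and p-values were adjusted by the Benjamini-Hochberg method. Fold changes on this scale understate the change of low genes. Gene lists with at least 3 tested members (33 of 36) were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry, and counts of members are given over all genes tested and adjusted over the list alone. A call lost with an estimated correlation does not by itself show that members vary together. Fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The groups, the gene lists, the comparisons, the naming rule and most alternatives were fixed before the data were examined.

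Genes were named by rule: passing genes of Polycomb repressive complex 2 and H3K27 enzymes with Ezh2, Eed and Suz12 in any case; the 10 largest rises and falls with no overlap between arms and at least 1 CPM in the higher arm; up to 4 passing members per list by adjusted p, or the most abundant member where none passed; Wnt and Hedgehog genes bivalent in DMSO; and the 3 widest H3K27me3 peaks of the DMSO list. Names outside this rule are marked as singled out later. Where genes have near-identical copies or overlap others, the values are uncertain, since reads could be split or shared.

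Peaks were compared by an overlap of at least 1 bp with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Chance overlap came from 100 copies of a list shifted along the chromosomes. With no strand at hand, a window reached 1 kb to each side of both gene ends. A gene was called bivalent where both marks overlapped the same window. States were set against RNA changes with camera and with Fisher's exact test across genes (scipy 1.17.1), with 95% intervals of odds ratios. Figures were drawn with matplotlib 3.10.9.

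The alternatives were other filters, median-of-ratios scaling, pseudocounts of 0.01, 0.5 and 1 RPKM, voom on recovered reads, a test against a 1.5-fold change, a replicate block, leaving out each library, other overlaps and windows, peaks of at least 400 bp, protein-coding genes only and whole genes. The RNA test was tested on simulated reads for 14202 genes in the same 2 arms. It recovered 50% of genes changed 1.5-fold, 88% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, with 6.70% false calls among 179. With no changed gene it made 0 calls, and 5 of 200 random sets had a camera p under 0.05. Simulated genes were drawn independently with 1 dispersion (0.0101) for all. The simulation therefore cannot show how camera behaves on lists whose members vary together, or the recovery of genes with a larger spread. Replicate libraries of each arm differed beyond sampling noise (chi-square per gene from 6.47 to 61.7), so none was counted as a copy of another. Results of 2 single genes are not reported here.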

Results

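Gene expression and 2 histone marks were measured in MC3T3-E1 subclone 4 cells, a line of pre-osteoblasts from mouse calvaria, on day 3 of culture in osteogenic medium. The cells had received 2.5 µM EPZ6438, an inhibitor of the H3K27 methyltransferase EZH2, or 0.25% DMSO as vehicle. Whether the EPZ6438 arm also held DMSO is not stated in the labels, so a difference in vehicle between the arms is not ruled out. RNA was sequenced from 3 samples of each arm. Chromatin immunoprecipitation covered H3K27me3, the repressive mark written by EZH2, and H3K4me3, a mark of active and poised promoters. Reads in genes numbered 18807156, 22221007 and 25365513 in the DMSO libraries and 21044111, 24140050 and 20023137 in the EPZ6438 libraries, and 18289 to 19196 genes per library had at least 1 read. The labels give 2 samples per mark and arm, of which only 1 merged peak list per mark and arm was analysed, so peak results carry no replicate error and the depth behind them is unknown here. Expression values are given as mean ± SD of RPKM over the 3 libraries of an arm, and changes as log2 differences of RPKM + 0.1, EPZ6438 minus DMSO. The samples were not stated to be separate cultures, so p-values measure only the spread between these samples, which may be technical.

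The first comparison asked which genes changed in expression when EZH2 was inhibited. Among the genes that rose most were Slc8a3, a sodium-calcium exchanger, Eln, which encodes elastin, Hpse, which encodes heparanase, Cd200, a cell surface glycoprotein, and Ifitm5, a membrane protein of osteoblasts. Slc8a3 rose from 0.805 ± 0.0575 to 9.13 ± 0.398 RPKM (log2 change 3.35, SE 0.12, limma adjusted p = 8.15e-05). Ifitm5 rose from 6.88 ± 1.27 to 64.8 ± 8.97 RPKM (log2 change 3.22, SE 0.15, adjusted p = 0.000198), and Hpse from 0.517 ± 0.0316 to 5.80 ± 0.754 RPKM. Among the genes that fell most were Nov, a matricellular protein of the CCN family, the chemokine Ccl2 and the cadherin Cdh26. Nov went from 185 ± 4.76 to 51.5 ± 2.70 RPKM (log2 change -1.84, SE 0.07, adjusted p = 8.15e-05) and Ccl2 from 4.29 ± 0.210 to 1.01 ± 0.396 RPKM (log2 change -2.04, SE 0.24, adjusted p = 0.00381).

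In all, 1001 of 14213 tested genes changed at an adjusted p under 0.05, 540 rising and 461 falling. A change of at least 2-fold was seen in 247 rising and 91 falling genes, and of at least 4-fold in 47 rising and 2 falling genes. The 338 genes changed at least 2-fold became 178 and 119 with pseudocounts of 0.5 and 1 RPKM, and 219, 211 and 199 without EPZ6438 replicate 1, 2 and 3. The other members of the 10 largest rises were Hoxb13 (log2 change 3.21, SE 0.19), the imprinted noncoding RNA H19 (3.00, SE 0.26), Fam167a (2.94, SE 0.27), the collagen gene Col11a2 (2.91, SE 0.32) and the transcription factor gene Grhl3 (2.88, SE 0.26). Also among the 10 largest falls were BC025446 (-2.82, SE 0.25), Ly6f (-1.93, SE 0.16), the chemokine Ccl7 (-1.89, SE 0.32), Ly6c1 (-1.83, SE 0.23) and the interferon-induced genes Oasl2 (-1.83, SE 0.30) and Rtp4 (-1.80, SE 0.25). Values of Ly6f and Ly6c1 are uncertain because reads can be shared within the Ly6 family. Whether reads of H19 were kept apart from those of antisense transcripts is unknown, since the strand setting of counting is not given. In each of the 1001 genes the 3 values of one arm lay wholly outside those of the other, which held for 26.7% of tested genes where chance gives 10%. The count was 628 with no filter on low counts (355 rising and 273 falling) and 118 in a test against a 1.5-fold change (101 and 17). It was 335 without DMSO replicate 2 (242 and 93), 381 without EPZ6438 replicate 1 (214 and 167), 372 without EPZ6438 replicate 2 (233 and 139) and 309 without EPZ6438 replicate 3 (190 and 119). The calls of Ccl7 and Oasl2 ended without a filter and without single libraries (adjusted p from 0.0512 to 0.0753).

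The RNA of the drug's target was close in both arms. Ezh2 was at 14.4 ± 1.79 RPKM in DMSO and 14.8 ± 0.676 RPKM in EPZ6438 (log2 change 0.05, SE 0.11, adjusted p = 0.839). Its partners in Polycomb repressive complex 2, Eed (log2 change -0.14, SE 0.14, adjusted p = 0.613) and Suz12 (-0.06, SE 0.15, adjusted p = 0.867), did not pass the test either. Of 14 tested genes for this complex and for H3K27 enzymes, only Phf19, an accessory subunit, passed, rising from 0.336 ± 0.0661 to 0.791 ± 0.0572 RPKM (log2 change 1.04, SE 0.18, adjusted p = 0.0171; 2 rose and 0 fell adjusted over the list alone). The list as a whole did not differ from other genes by camera (adjusted p = 0.963), and its median (-0.09) and mean (0.04) differed in sign. The call of Phf19 ended without a filter on low counts, and without any 1 of the EPZ6438 libraries (adjusted p from 0.0622 to 0.0815).

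Osteoblast markers rose as a group. Phospho1, a phosphatase that starts matrix mineralization, rose from 28.0 ± 3.29 to 164 ± 10.2 RPKM (log2 change 2.55, SE 0.10, adjusted p = 8.15e-05). Smpd3, a sphingomyelinase needed for mineralization, rose from 11.8 ± 2.56 to 82.6 ± 6.71 RPKM (2.81, SE 0.16), Ibsp, which encodes bone sialoprotein, from 193 ± 20.8 to 587 ± 15.5 RPKM (1.61, SE 0.10), and Tnfrsf11b, which encodes osteoprotegerin, from 39.7 ± 5.03 to 147 ± 9.28 RPKM (1.89, SE 0.11). Of 28 tested osteoblast markers 16 rose, 2 fell and 10 did not pass (18 rose and 3 fell adjusted over the list alone), with a median log2 change of 0.80. Against other genes the list was higher by camera (adjusted p = 4.75e-14), and it was the only list that still passed with an estimated correlation (adjusted p = 0.0278 with an estimated correlation). The regulators of osteoblast differentiation Runx2 and Sp7 and the alkaline phosphatase gene Alpl were singled out after their values were seen. Runx2 rose from 30.4 ± 1.59 to 45.8 ± 3.05 RPKM (log2 change 0.59, SE 0.08, adjusted p = 0.00813), Sp7 from 54.1 ± 1.62 to 102 ± 3.25 RPKM (0.91, SE 0.07) and Alpl from 6.04 ± 0.370 to 13.4 ± 0.934 RPKM (1.14, SE 0.10). The call of Runx2 ended without DMSO replicate 2 (adjusted p = 0.0543) and without EPZ6438 replicate 3 (adjusted p = 0.0620).

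Some chondrocyte markers rose as well. Col2a1, the main collagen of cartilage, rose from 14.6 ± 4.07 to 91.0 ± 14.9 RPKM (log2 change 2.66, SE 0.22, adjusted p = 0.00110), and Hapln1, a link protein of cartilage matrix, from 3.34 ± 0.250 to 7.61 ± 0.375 RPKM (1.17, SE 0.11). Of 11 tested chondrocyte markers 5 rose, 0 fell and 6 did not pass (6 rose and 0 fell adjusted over the list alone), with a median log2 change of 0.36. The list was higher than other genes by camera (adjusted p = 7.93e-05), a call lost with the estimate from the data (adjusted p = 0.107 with an estimated correlation).

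**Figure D1:**
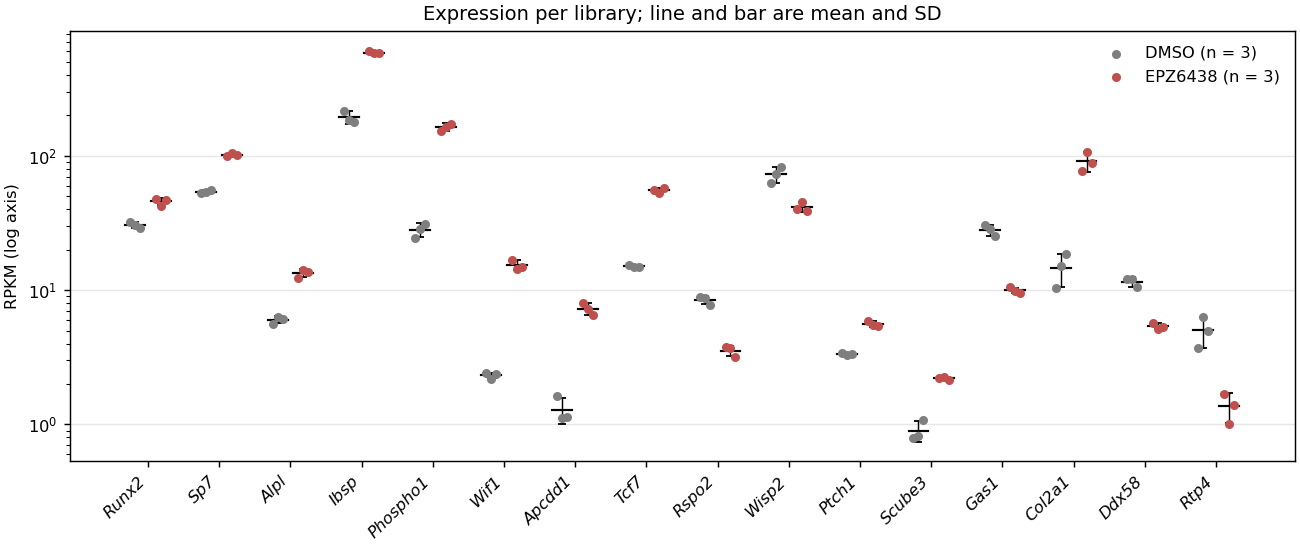
RPKM on a log axis for 16 genes in each of the 3 DMSO and 3 EPZ6438 libraries, each point a library, with the mean as a line and the SD as a bar. The points of both arms do not overlap for any gene shown. Phospho1 lies at 28.0 RPKM in DMSO and 164 RPKM in EPZ6438, and Gas1 at 28.0 and 9.95 RPKM.

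The title of the series names regulators of Wnt and Hedgehog signalling, so both pathways were examined as lists. Among Wnt antagonists, Wif1, which binds Wnt ligands, rose from 2.32 ± 0.116 to 15.4 ± 1.30 RPKM (log2 change 2.68, SE 0.11, adjusted p = 8.15e-05), and Apcdd1, a membrane-bound antagonist, from 1.29 ± 0.282 to 7.23 ± 0.743 RPKM (2.41, SE 0.17, adjusted p = 0.000640). Dkk3 went the other way, from 82.2 ± 2.20 to 52.8 ± 2.99 RPKM (-0.64, SE 0.07, adjusted p = 0.00355). Of 9 tested antagonists 5 rose, 3 fell and 1 did not pass (5 rose and 4 fell adjusted over the list alone), and the list did not differ from other genes by camera (adjusted p = 0.238). Among ligands and receptors, Wnt6 rose from 4.64 ± 0.295 to 9.93 ± 1.28 RPKM (1.08, SE 0.12, adjusted p = 0.00361) and Rspo2, a secreted enhancer of Wnt signalling, went from 8.44 ± 0.598 to 3.53 ± 0.305 RPKM (-1.23, SE 0.11, adjusted p = 0.00168). Of 25 tested ligands and receptors 7 rose, 2 fell and 16 did not pass (7 rose and 2 fell adjusted over the list alone), with a median log2 change of 0.32 and camera adjusted p = 0.0382. That call was lost with the estimate from the data (adjusted p = 0.188 with an estimated correlation), under median-of-ratios scaling (adjusted p = 0.0656), and without DMSO replicate 1 (0.0946), EPZ6438 replicate 2 (0.118) or EPZ6438 replicate 3 (0.0702).

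Among genes that respond to canonical Wnt signalling more rose than fell. Tcf7, a transcription factor of the pathway, rose from 15.0 ± 0.347 to 55.3 ± 1.91 RPKM (log2 change 1.87, SE 0.07, adjusted p = 8.15e-05), Rnf43, a ubiquitin ligase that removes Frizzled receptors, from 2.52 ± 0.365 to 6.80 ± 0.408 RPKM (1.40, SE 0.14), and Tnfrsf19 from 46.2 ± 3.34 to 87.8 ± 2.07 RPKM (0.93, SE 0.08). Wisp2, a CCN family member, went from 73.0 ± 9.98 to 41.5 ± 3.60 RPKM (-0.81, SE 0.12, adjusted p = 0.00929). Of 17 tested Wnt target genes 8 rose, 1 fell and 8 did not pass (12 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.45. The list was higher than other genes by camera (adjusted p = 7.52e-07), a call lost with the estimate from the data (adjusted p = 0.0719 with an estimated correlation). That estimate, -0.00327, was below the preset 0.01, so the loss does not show that members vary together. Axin2, a widely used Wnt reporter gene singled out after its values were seen, was at 4.44 ± 0.822 and 7.03 ± 0.842 RPKM (0.66, SE 0.16, adjusted p = 0.0568) and passed under some other settings, voom on recovered reads among them (adjusted p = 0.0297). The call of Wisp2 ended without DMSO replicate 2, EPZ6438 replicate 1 or EPZ6438 replicate 3 (adjusted p from 0.0505 to 0.0577).

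Hedgehog pathway genes moved in both directions. Scube3, a secreted protein that helps to release Hedgehog ligands, rose from 0.898 ± 0.153 to 2.20 ± 0.0438 RPKM (log2 change 1.22, SE 0.16, adjusted p = 0.00539), and Ptch1, the Hedgehog receptor and a target of the pathway, from 3.35 ± 0.0495 to 5.61 ± 0.294 RPKM (0.73, SE 0.10, adjusted p = 0.00804). Gas1, a co-receptor, went from 28.0 ± 2.61 to 9.95 ± 0.469 RPKM (-1.48, SE 0.10, adjusted p = 0.000515), and Foxf1 from 9.94 ± 0.0682 to 7.52 ± 0.401 RPKM (-0.40, SE 0.09, adjusted p = 0.0406). Of 22 tested members 2 rose, 2 fell and 18 did not pass (2 rose and 2 fell adjusted over the list alone), with a median log2 change of 0.06 and camera adjusted p = 0.867. Gli1, a direct target of the pathway singled out after its values were seen, was at 0.652 ± 0.198 and 0.841 ± 0.132 RPKM (0.35, SE 0.24, adjusted p = 0.476). The call of Ptch1 ended without DMSO replicate 2 (adjusted p = 0.0543) and that of Foxf1 without any 1 library (adjusted p from 0.0560 to 0.178). A replicate block also ended the call of Foxf1 (adjusted p = 0.0658).

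Ligands of the BMP and TGF-beta families and their antagonists were a further signalling list. Inhba, a subunit of activin, rose from 27.8 ± 1.28 to 48.0 ± 1.08 RPKM (log2 change 0.79, SE 0.07, adjusted p = 0.00152), Bmp4 from 26.6 ± 3.28 to 39.2 ± 3.00 RPKM (0.57, SE 0.11, adjusted p = 0.0298) and Smoc2 from 0.173 ± 0.0940 to 1.06 ± 0.203 RPKM (2.13, SE 0.27). Of 21 tested members 3 rose, 0 fell and 18 did not pass (7 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.27. The list was higher than other genes by camera (adjusted p = 0.0162), a call lost with the estimate from the data (adjusted p = 0.178 with an estimated correlation). Among 18 tested targets of these ligands 5 rose and 2 fell (6 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.101), with Bambi, a decoy receptor, at 1.53 (SE 0.15), Ctgf at 1.04 (SE 0.11) and Id4 at -1.30 (SE 0.13). The call of Bmp4 ended without a filter and without DMSO replicate 2 or any 1 EPZ6438 library (adjusted p from 0.0603 to 0.138).

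Among interferon response genes more fell than rose. Ddx58, which encodes the RNA sensor RIG-I, went from 11.5 ± 0.943 to 5.40 ± 0.288 RPKM (log2 change -1.08, SE 0.10, adjusted p = 0.00178), Gbp2, a guanylate-binding protein, from 4.59 ± 0.438 to 1.97 ± 0.116 RPKM (-1.18, SE 0.13) and Rtp4 from 5.01 ± 1.30 to 1.36 ± 0.347 RPKM. Xaf1 was the 1 member that rose, from 5.24 ± 0.638 to 10.2 ± 0.574 RPKM (0.96, SE 0.12, adjusted p = 0.00456). Of 21 tested members 1 rose, 7 fell and 13 did not pass (1 rose and 18 fell adjusted over the list alone), with a median log2 change of -0.87. The list was lower than other genes by camera (adjusted p = 1.18e-08), a call lost with the estimate from the data (adjusted p = 0.178 with an estimated correlation).

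**Figure D2:**
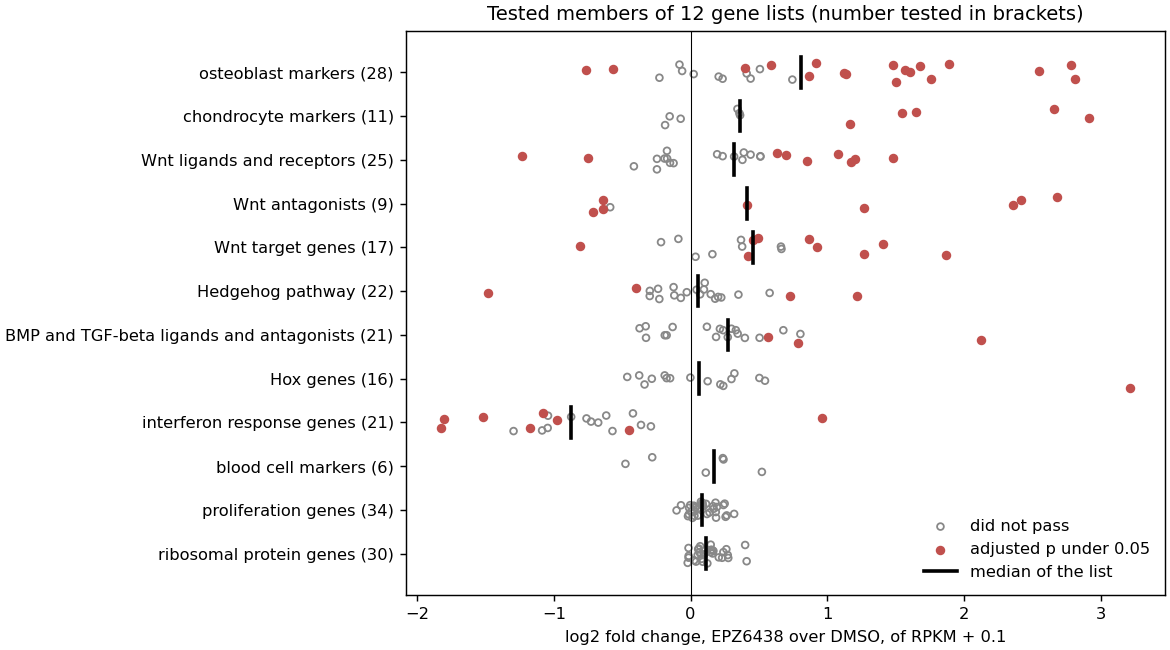
Log2 fold change, EPZ6438 over DMSO, of RPKM + 0.1 for each tested member of 12 gene lists, with filled points for genes past the test and a vertical line at each list's median. The osteoblast markers have a median of 0.80 and the interferon response genes of -0.87, while proliferation genes lie close around 0.09.

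Lists of other cell types and of growth served as a background. Of 6 tested blood cell markers, 6 endothelial markers and 6 adipocyte markers none passed the limma test, and camera adjusted p was 0.683, 0.258 and 0.664 (0 rose in each and 0, 0 and 1 fell adjusted over the list alone). Acta2, the smooth muscle actin gene, was the 1 of 9 smooth muscle and myofibroblast markers to fall (log2 change -0.47; 4 fell adjusted over the list alone; camera adjusted p = 0.0979). Des, which encodes desmin, was the 1 of 3 skeletal muscle markers to rise (0.88; 3 rose adjusted over the list alone), and that list passed camera (adjusted p = 0.0124) but not with the estimate from the data (adjusted p = 0.178 with an estimated correlation). Tubb3, a neuronal tubulin, rose from 8.00 ± 1.12 to 33.6 ± 4.24 RPKM (2.06, SE 0.14) as the 1 of 9 neuronal genes to pass (2 rose adjusted over the list alone; camera adjusted p = 0.324; median -0.11 and mean 0.20, which differ in sign). None of 34 tested proliferation genes and none of 30 ribosomal protein genes passed the limma test, and none did so adjusted over the list alone. Their small median shifts of 0.09 and 0.11 passed camera (adjusted p = 0.00528 and 0.0124) and were lost with the estimate from the data (adjusted p = 0.353 and 0.544 with an estimated correlation). Across all genes 2927 had an unadjusted p under 0.05 and voom called 1168. The calls of Acta2 and Des ended without a filter and without most single libraries (adjusted p from 0.0771 to 0.255). The call of the proliferation list ended without DMSO replicate 3 (adjusted p = 0.0587), and that of the ribosomal list without DMSO replicate 1 or 2 or EPZ6438 replicate 2 (from 0.0574 to 0.0945). Smooth muscle and myofibroblast markers passed camera as lower without DMSO replicate 1 (adjusted p = 0.0132) and without EPZ6438 replicate 2 (0.0277).

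The second comparison asked how the regions with H3K27me3 differed between arms. The DMSO list held 143399 H3K27me3 peaks that covered 89.4 Mb, and the EPZ6438 list 20764 peaks that covered 11.6 Mb, or 14.5% as many. The widest peak of the DMSO list spanned 12062 bp on chromosome 19 (45284141 to 45296202, mm10), 48329 bp from Lbx1, a homeobox gene. The next widest lay on chromosome 6 (42645643 to 42656504), 389 bp from Fam115c, and on chromosome 10 (80490540 to 80500184) across Onecut3, a transcription factor gene. Of the DMSO peaks 10.8% were overlapped by an EPZ6438 peak, against 1.11% for shifted copies of the lists, and of the EPZ6438 peaks 76.1% overlapped a DMSO peak, against 7.73% for shifted copies. With at least 50% of a peak required to overlap, the share of DMSO peaks was 5.48%. Peak numbers depend on depth, caller settings and how lists were merged, and the merged lists left no replicates to test between arms.

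The H3K4me3 lists differed in another way. There were 40113 H3K4me3 peaks in DMSO that covered 10.4 Mb with a median width of 212 bp, and 16216 in EPZ6438 that covered 8.22 Mb with a median width of 401 bp. Within 1 kb of a gene end lay 23.5% of the DMSO peaks (shifted copies 5.73%) and 72.2% of the EPZ6438 peaks (shifted copies 6.32%). The widest EPZ6438 peaks lay across Bbc3 (3388 bp), a proapoptotic gene, and across Runx2 (chromosome 17, 44733420 to 44736758, 3339 bp), both singled out after their values were seen. Of the DMSO peaks 23.7% were overlapped by an EPZ6438 peak, and of the EPZ6438 peaks 53.2% overlapped a DMSO peak. Narrow peaks made up most of the DMSO list, 67.1% being under 250 bp, and among peaks of at least 400 bp the order was turned, with 223% as many in EPZ6438 as in DMSO. The shares overlapped turned as well, to 66.9% of such DMSO peaks and 29.8% of such EPZ6438 peaks.

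**Figure D3:**
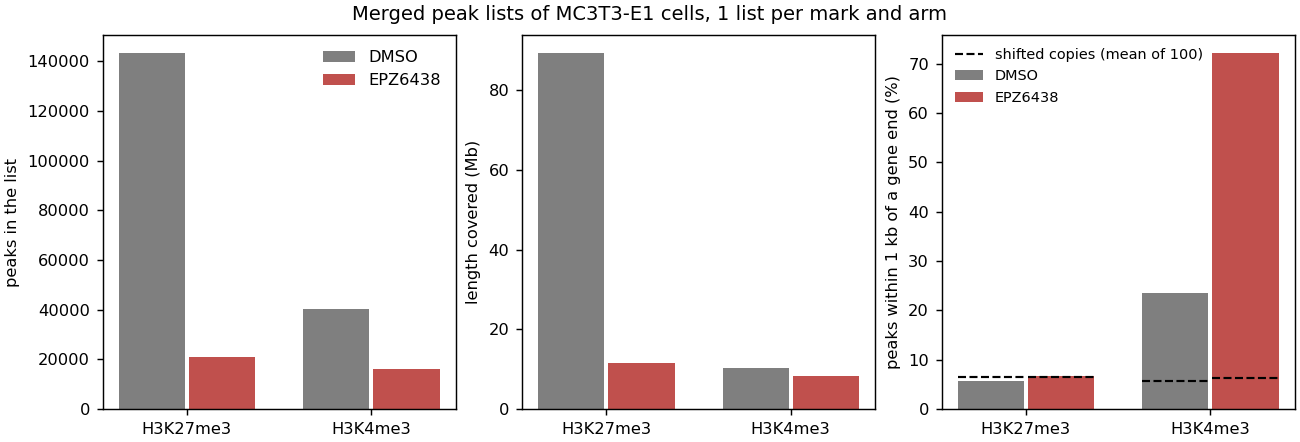
Number of peaks, length covered in Mb and percent of peaks within 1 kb of a gene end for the merged H3K27me3 and H3K4me3 lists of the DMSO and EPZ6438 arms, with dashed lines for the mean of 100 shifted copies. H3K27me3 covers 89.4 Mb in DMSO and 11.6 Mb in EPZ6438, and the share of H3K4me3 peaks at gene ends is 23.5% in DMSO and 72.2% in EPZ6438.

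Both marks together at a gene end, the bivalent state, were then counted. Of 43309 genes, 1011 had both marks within 1 kb of the same gene end in DMSO and 36 in EPZ6438, and 20 genes had them in both arms, Phf19 among them. In DMSO these were 2.33% of genes, where H3K4me3 lay at 20.2% and H3K27me3 at 16.2%. No chance level was computed for this count of genes. Of the 1011 genes, 524 had neither mark in EPZ6438, 236 had H3K27me3 only and 225 had H3K4me3 only. H3K27me3 alone or with H3K4me3 lay at 6997 genes in DMSO and 1384 in EPZ6438, while H3K4me3 lay at 8765 and 10589. A missing H3K4me3 peak in DMSO need not mean a missing mark. Of 30 ribosomal protein genes, none of which passed the limma test, 19 had an H3K4me3 peak in DMSO and 28 in EPZ6438. Of 5818 genes with H3K27me3 only in DMSO, 4784 had neither mark in EPZ6438, 873 kept H3K27me3 only and 144 had H3K4me3 only. The window set these numbers, with 3054 bivalent genes in DMSO at 2.5 kb each side, 38 where peaks had to cover at least 25% of the window and 72 with peaks of at least 400 bp. Peaks with both marks were not concentrated there: of the DMSO H3K4me3 peaks that overlapped an H3K27me3 peak 4.68% lay within 1 kb of a gene end (shifted copies 5.68%), as did 5.72% of all DMSO H3K27me3 peaks (shifted copies 6.46%). Strand was not used, so a gene end can be either end of the gene and not only its promoter.

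In these windows 35 gene lists with positions were compared with all other genes by Fisher's exact test across genes. Wnt ligands and receptors carried H3K27me3 in DMSO at 16 of 41 genes (39.0%, against 16.1% of other genes; odds ratio 3.33, 95% interval 1.66 to 6.48, exact adjusted p = 0.00649), and Wnt antagonists at 8 of 18 (44.4%; odds ratio 4.16, exact adjusted p = 0.0191). The Hedgehog pathway carried it at 8 of 34 genes (23.5%; odds ratio 1.60, 95% interval 0.625 to 3.64, exact adjusted p = 0.532). Of all 6997 genes with H3K27me3 in DMSO 5834 (83.4%) had none at their ends in EPZ6438. The same held for 9 of the 16 Wnt ligands and receptors (56.2%), 5 of the 8 antagonists (62.5%) and 6 of the 8 Hedgehog genes (75%), shares below that of all genes that did not pass as lower (odds ratios 0.255, 0.332 and 0.598; exact adjusted p = 0.214, 0.643 and 1.00 in a test added after the values were seen). Shh and Gli2, singled out after their values were seen, were the Hedgehog genes that kept a peak. Hox genes (14 of 39, exact adjusted p = 0.0191) and other developmental transcription factors (41 of 120, exact adjusted p = 4.30e-05) were also marked more often. So were lists with no link to the title, namely germline genes (8 of 18), blood cell markers (9 of 21) and Notch pathway genes (9 of 21), each at exact adjusted p = 0.0191, neuronal genes (13 of 38, 0.0243), and epithelial (7 of 17) and skeletal muscle markers (8 of 21), both at 0.0412. Proliferation genes were marked less often (0 of 34, exact adjusted p = 0.0191). Of these 11 calls only those of Wnt ligands and receptors (exact adjusted p = 0.00487) and developmental transcription factors (0.0268) held where peaks had to cover at least 25% of the window, and with peaks of at least 400 bp these (0.0301 and 0.00151) and that of neuronal genes (0.0375). The call of the antagonists ended in both settings (0.107 and 0.160), and those of epithelial and skeletal muscle markers also ended among protein-coding genes (0.0559 each).

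Bivalent Wnt genes in DMSO were Wnt3a, Wnt5a, Wnt8b and the antagonist Draxin, and no gene of the Hedgehog list was bivalent within 1 kb. In EPZ6438 Wnt5a had H3K4me3 only and the other 3 had H3K27me3 only, and Wnt5a, the 1 of them with enough reads, was at 0.397 ± 0.0297 and 0.576 ± 0.0850 RPKM (log2 change 0.44, SE 0.17, limma adjusted p = 0.209). Across the genome DMSO H3K4me3 peaks that overlapped H3K27me3 seldom recurred. An EPZ6438 H3K4me3 peak overlapped 1.42% of them, against 44.2% of the other DMSO H3K4me3 peaks, which limits what a bivalent call means. No list passed for the bivalent state, the nearest by adjusted p being BMP and TGF-beta ligands and antagonists (4 of 31) and genes for Polycomb repressive complex 2 and H3K27 enzymes (3 of 15), each at exact adjusted p = 0.0984. At 2.5 kb each side 4 lists passed, Wnt ligands and receptors among them (9 of 41, exact adjusted p = 0.0453). There 3 of 34 Hedgehog genes were bivalent in DMSO (exact adjusted p = 0.853), namely Shh, Smo and Gli1, named after their values were seen, and none of the 3 was in EPZ6438.

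Within 1 kb of their ends Wif1, Ror2 and Scube3 had H3K27me3 only in DMSO and H3K4me3 only in EPZ6438, Ror2 being singled out after its values were seen. These states are peak calls, and the DMSO list may have missed H3K4me3 there. At Wif1 (chromosome 10, 121033960 to 121100650) the nearest DMSO H3K27me3 peak (121032639 to 121032976) lay 984 bp outside the gene, and the EPZ6438 H3K4me3 peak (121033922 to 121034165) covered that gene end. At Scube3 (chromosome 17, 28142316 to 28174852) a DMSO H3K27me3 peak covered the gene end (28141765 to 28142801), where EPZ6438 had an H3K4me3 peak (28142352 to 28142811). Farther from the ends the marks did not switch in full. Inside Wif1 lay 1 EPZ6438 H3K27me3 peak (185 bp), and inside Scube3 3 such peaks (278, 700 and 377 bp) and 2 DMSO H3K4me3 peaks (279 and 177 bp), with a further DMSO H3K4me3 peak of 480 bp 2479 bp outside the gene. At 2.5 kb Scube3 had both marks in DMSO, at different ends. Both genes rose in RNA, and Ror2, a Wnt receptor, did not pass (log2 change 0.51, limma adjusted p = 0.210).

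**Figure D4:**
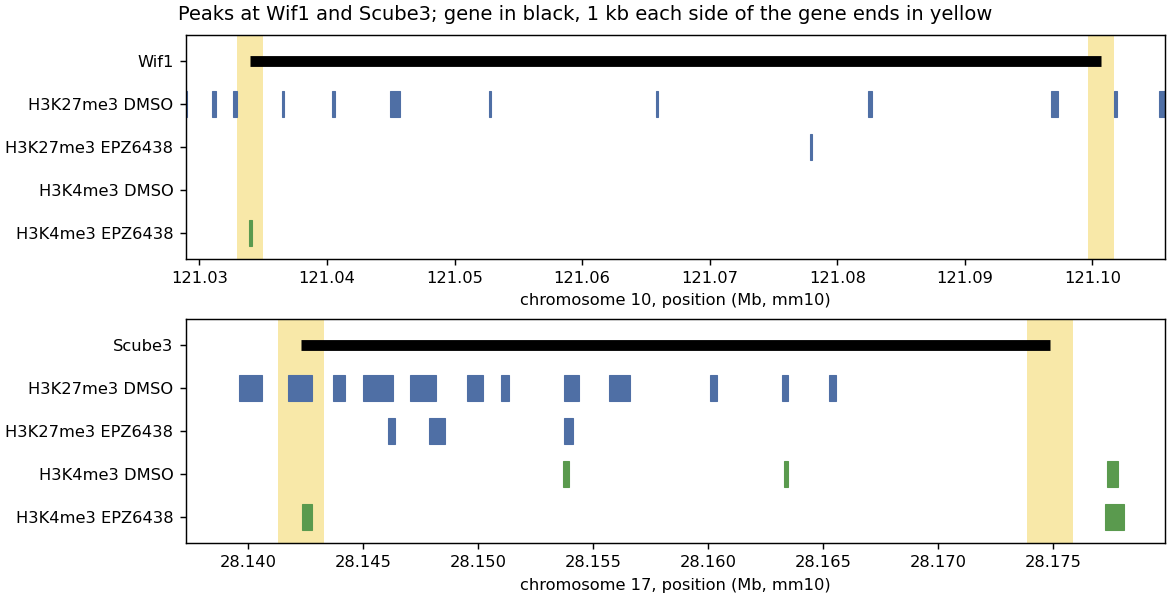
Peaks of both marks in both arms along Wif1 on chromosome 10 and Scube3 on chromosome 17 (positions in Mb, mm10), with the gene in black and the windows of 1 kb each side of its ends in yellow. In EPZ6438 an H3K4me3 peak of 244 bp lies at the end of Wif1 and one of 460 bp at the end of Scube3.

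The last comparison asked whether genes with H3K27me3 in vehicle cells changed in RNA. Genes that had H3K27me3 at a gene end in DMSO and not in EPZ6438 rose in 111 of 981 tested cases (11.3%), against 3.24% of other genes, and fell in 15. Slc8a3, Eln, Cd200, Hpse, H19 and Grhl3 were among them, while Hoxb13 and Fam167a kept a peak, and Ifitm5 and Col11a2 had neither mark in either arm. Of genes with both marks in DMSO 37 of 292 rose (12.7%), and of genes with H3K27me3 only 95 of 722 rose (13.2%). The odds ratio of rising was 3.81 for genes that lost the peak (95% interval 3.03 to 4.76), 3.87 for both marks (2.63 to 5.55) and 4.44 for H3K27me3 only (3.47 to 5.64), by Fisher's exact test across genes, which are not independent replicates. As sets these genes were higher than others by camera (adjusted p = 0.000314, 0.00118 and 8.50e-05), and all 3 calls held with an estimated correlation (adjusted p = 0.0236 for each). Their median log2 changes were small, at 0.054, 0.075 and 0.077, against -0.029 over all tested genes. Most of their genes, 855 of 981, 250 of 292 and 617 of 722, did not pass the limma test. A gain of H3K4me3 here means a peak called in EPZ6438 and not in DMSO, which may be a missed DMSO call. Of genes with such a gain 98 of 2689 rose and 86 fell (odds ratio of rising 0.948, exact adjusted p = 0.772, camera adjusted p = 0.795). They rose less often than other genes where peaks had to cover at least 25% of the window (odds ratio 0.675, exact adjusted p = 0.000904), with peaks of at least 400 bp (0.789, 0.0295) and over whole genes (0.740, 0.0410). Those with H3K27me3 only in DMSO rose in 17 of 100 cases (odds ratio 5.32, camera adjusted p = 2.34e-05, and 0.0236 with an estimated correlation), a set test that did not pass at 25% of the window (0.0890) or over whole genes (0.106).

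Genes that kept H3K27me3 in EPZ6438 rose more often than genes that lost it. Of 116 such genes, Hoxb13 among them, 23 rose (19.8%), and the odds ratio of lost over kept was 0.516 (Fisher's exact p = 0.0154, two-sided). This call ended where peaks had to cover at least 25% of the window (odds ratio 0.755, exact p = 0.575) and with peaks of at least 400 bp (0.712, exact p = 0.373). It held at 2.5 kb (0.368, exact p = 6.33e-08), over whole genes (0.392, exact p = 8.12e-11) and among protein-coding genes (0.413, exact p = 0.00177). Among genes with neither mark in DMSO 236 of 6441 rose (3.66%) and 262 fell (4.07%), and of the 10 largest falls only Oasl2 and Nov carried a mark, Oasl2 both marks in DMSO and Nov H3K4me3 in both arms. The set test for genes with both marks did not pass where peaks had to cover at least 25% of the window (adjusted p = 0.0784), and over whole genes neither it (0.105) nor the test for genes that lost the peak (0.117) passed.

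**Figure D5:**
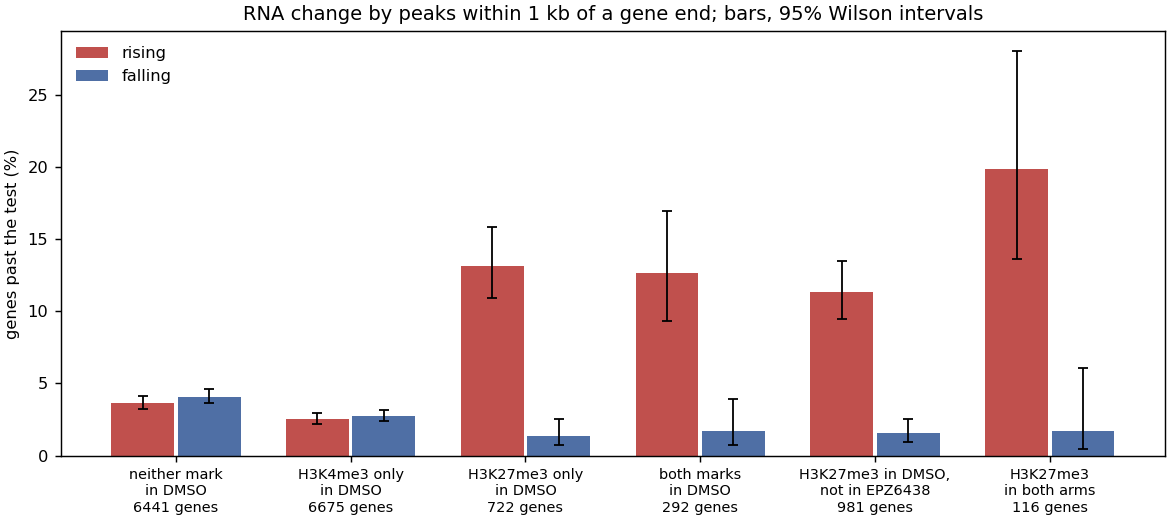
Percent of tested genes that rose or fell in RNA with EPZ6438, by the peaks within 1 kb of a gene end, with 95% Wilson intervals for counting error only and the number of genes under each group. Of genes with H3K27me3 in both arms 19.8% rose, and of genes with neither mark in DMSO 3.66%.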

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

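The pseudocounts, voom, peaks of at least 400 bp, protein-coding genes only, whole genes, scaling in the list and state tests, and the odds of lost over kept were chosen only after the result was seen. Where a value below differs from the report, the cause was not tested unless fewer samples, genes or peaks made the setting. At this depth and 3 samples per arm a change of 1.5-fold was recovered in 50% of simulated genes, and in 64% by voom, so many small changes are missed. Other depths and sample numbers were not simulated, and the peak lists give no depth.

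Of 1471 values of named genes under other settings 1306 kept direction and side of the threshold, 153 did not pass any more, 2 passed newly and 10 turned; all 10 were of genes that had not passed. For gene lists 273 of 330 were the same, 25 were lost, 9 passed newly and 23 turned, and for sets by state 133 of 150 were the same, 13 were lost and 4 turned. Of the genes singled out later, 5 were run under these settings, namely Runx2, Sp7, Alpl, Axin2 and Gli1. For them 67 of 75 values were the same, with 4 passing newly and 4 lost. Of the 1001 changed genes none turned direction in a setting that tested it, which were 938 under the stricter filter, 989 without a DMSO library, 941 without an EPZ6438 library and 1001 in the others.

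Changed genes numbered 628 with no filter, where 23146 genes were tested, and 118 against a 1.5-fold change, which kept 35 of the named genes. Genes changed at least 2-fold numbered 178 and 119 with pseudocounts of 0.5 and 1 RPKM. Leaving out 1 library, which leaves fewer samples, gave 309 to 1003 changed genes, 199 to 357 changed at least 2-fold and 55 to 84 named genes that passed. Small changes turned in this way for Suz12 (-0.19 to 0.0877), Kdm5c (-0.0416 to 0.0917), Fasn (-0.15 to 0.31), Krt14 (-0.0379 to 0.20), Ezh2 (-0.0379 to 0.14) and Top2a (-0.0868 to 0.12).

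The labels give both arms the same replicate numbers but do not say that a number marks a shared culture, so no pairs were planned. The deviations of same-numbered samples correlated at 0.41, 0.08 and 0.06, and those of other pairs at -0.41 to 0.33. These values do not rule out that the numbers mark pairs. DMSO replicates 1 and 2 correlated best with their own number and DMSO replicate 3 with EPZ6438 replicate 2 (0.33). A replicate block gave 1051 genes, 853 of them among the 1001, ended 3 calls of named genes and added 1, and left the immediate early genes at adjusted p = 0.0504.

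Of 12 lists past camera 1 passed with an estimated correlation, where adjusted p was 0.188 for Wnt ligands and receptors, 0.0719 for Wnt target genes and 0.178 for interferon genes. The estimate was below the preset 0.01 for Wnt ligands and receptors (-0.00477), Wnt targets (-0.00327), chondrocyte markers (-0.0240) and BMP and TGF-beta ligands (-0.0451). It was also below for p53 targets (-0.0413), stress genes (-0.0321) and skeletal muscle markers (-0.296). It was above for interferon (0.218), ribosomal protein (0.253), immediate early (0.0854) and proliferation genes (0.0694). Scaling left Wnt ligands and receptors at 0.0656. By fry, which does not compare a list with other genes, proliferation (adjusted p = 0.0764) and ribosomal protein genes (0.259) did not pass. The others of the 12 lists did, with 0.00874 for Wnt ligands and receptors, 0.000446 for Wnt targets and 0.00576 for interferon genes. Fry gave 0.000286 for Wnt antagonists, and turned the direction of the Polycomb repressive complex 2 list (0.749), the Hedgehog list (0.749) and CDK inhibitors (0.259). Without 1 library adjusted p ran from 0.0336 to 0.118 for Wnt ligands and receptors. Lists that had not passed turned direction in this way, with adjusted p from 0.654 to 0.999 for Polycomb repressive complex 2, 0.470 to 0.952 for Hedgehog, 0.327 to 0.889 for developmental transcription factors, 0.393 to 0.952 for Notch, 0.583 to 0.972 for H3K4 methyltransferase complexes, 0.767 to 0.967 for CDK inhibitors, 0.114 to 0.967 for extracellular matrix, 0.242 to 0.868 for adipocyte markers, 0.746 to 0.972 for Polycomb repressive complex 1, 0.491 to 0.991 for imprinted genes, 0.336 to 0.952 for Hox genes and 0.639 to 0.952 for cholesterol synthesis.

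Of sets by state, 7 passed at first, 3 with peaks over at least 25% of the window and 2 over whole genes. Adjusted p for both marks was 0.0784 and 0.105 there, and 0.117 for lost H3K27me3 over whole genes. The H3K4me3 only set turned without passing at 25% of the window (0.720), with peaks of at least 400 bp (0.861) and without 1 library (0.763 to 0.989), as did the set that gained H3K4me3 with such peaks (0.861). At 25% of the window the odds ratio of rising was 4.62 for both marks and no longer passed, with 38 bivalent genes left, and 0.755 for lost over kept, which was 0.712 with peaks of at least 400 bp. At 2.5 kb 4 lists passed for the bivalent state and 1 for its loss, and for any H3K27me3 2 lists passed at 25% of the window and 3 with peaks of at least 400 bp.

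With at least 50% of a peak overlapped, 5.48% of DMSO and 60.7% of EPZ6438 H3K27me3 peaks were shared, and 22.7% and 36.6% of H3K4me3 peaks. With peaks within 1 kb joined, 11.3% of DMSO H3K27me3 peaks and 21.2% and 62.8% of H3K4me3 peaks were shared. With peaks of at least 400 bp, the shares were 10.1% and 68.2% for H3K27me3 and 66.9% and 29.8% for H3K4me3, whose EPZ6438 peaks were then 223% of the DMSO number. Bivalent genes in DMSO and EPZ6438 numbered 3054 and 105 at 2.5 kb, 38 and 1 at 25% of the window, 72 and 4 with peaks of at least 400 bp, and 608 in DMSO among protein-coding genes. Genes with H3K27me3 numbered 12193 and 2581 at 2.5 kb, 2647 and 520 at 25%, 4301 and 863 at 400 bp, and 3749 and 803 when protein-coding. Genes with H3K4me3 in DMSO and EPZ6438 numbered 2670 and 7104 at 25% and 2863 and 7768 at 400 bp. Over whole genes the order turned, with 12571 and 11558.

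The planned DESeq2 Wald test was left out, because the deposited unit is RPKM, and voom on recovered reads was run in its place. The stricter peak score was not run, because the lists hold no score. The planned scaling and fold tests were run with median-of-ratios factors and limma's treat.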

Other observations

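The tests of peak position by gene ends, matched expression, scaling, lost against kept peaks, single libraries, blood cell markers, correlated interferon genes, the DMSO input and splits of the gene count were chosen only after the result was seen.

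Single genes of other lists changed too. Cdkn1a, the inhibitor of cyclin-dependent kinases induced by p53, rose from 104 ± 3.94 to 192 ± 6.69 RPKM (log2 change 0.89, SE 0.07, adjusted p = 0.000974), while Cdkn2c (-0.51, SE 0.07) and Cdkn1b (-0.51, SE 0.09) fell. Of 4 tested inhibitors of this kind 1 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.883; median -0.14 and mean 0.03, which differ in sign). Of 16 tested p53 targets 1 rose and 0 fell (3 rose adjusted over the list alone), with camera adjusted p = 0.00104 and adjusted p = 0.111 with an estimated correlation. Among 20 genes of the unfolded protein and amino acid responses 5 rose, Xbp1 (0.71) and Asns (0.58) among them (6 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.00163 and adjusted p = 0.111 with an estimated correlation. Among 18 immediate early genes 4 rose, with Klf4 at 0.92 and Nr4a3 at 1.53, and 1 fell (6 rose and 1 fell adjusted over the list alone). That list passed camera (adjusted p = 0.0382) but not with the estimate from the data (adjusted p = 0.440 with an estimated correlation) or under median-of-ratios scaling (0.0656). Without DMSO replicate 1 its adjusted p was 0.236 and without EPZ6438 replicate 2 it was 0.105. Without DMSO replicate 2 or EPZ6438 replicate 3 the calls of Cdkn2c, Cdkn1b, Xbp1 and Asns also ended (adjusted p from 0.0543 to 0.115).

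Growth factors, matrix genes and developmental regulators moved in both directions, and none of their lists passed camera. Igf1 went from 14.1 ± 1.96 to 6.00 ± 0.519 RPKM (log2 change -1.21, SE 0.13) and Fgf7 from 37.2 ± 6.73 to 19.2 ± 1.39 RPKM (-0.94, SE 0.14), and 3 of 21 genes of FGF and IGF signalling rose and 2 fell (7 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.324). Tnc, which encodes tenascin C, rose from 124 ± 4.41 to 232 ± 1.25 RPKM (0.90, SE 0.07) and the fibrillin gene Fbn1 fell (-0.75), among 36 matrix genes of which 5 rose and 6 fell (6 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.748; median -0.09 and mean 0.06, which differ in sign). Tbx2 rose from 0.864 ± 0.187 to 3.97 ± 0.628 RPKM (2.08, SE 0.20) and Six2 fell (-0.72), among 52 developmental transcription factors of which 6 rose and 3 fell (10 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.813; median -0.11 and mean 0.13, which differ in sign). Plagl1, an imprinted zinc finger gene with H3K27me3 in DMSO only, rose from 20.7 ± 1.12 to 43.4 ± 0.760 RPKM (1.07, SE 0.07), and of 16 imprinted genes 4 rose and 1 fell (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.683; median -0.02, mean 0.20). The Notch ligand Jag1 fell by 0.83 on the log2 scale as the 1 of 12 Notch pathway genes to pass (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.664). Without DMSO replicate 2 or EPZ6438 replicate 3 the call of Fgf7 ended (adjusted p = 0.0590 and 0.0594).

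In the DMSO arm 19247 of 40113 H3K4me3 peaks (48.0%) overlapped an H3K27me3 peak, against 5.74% for shifted copies, and 1.42% of them were overlapped by an EPZ6438 H3K4me3 peak. Promoters that carry both marks are argued against as the main source, since 4.68% of these peaks lay at gene ends, below the 5.68% of shifted copies, while 40.8% of the other DMSO H3K4me3 peaks did. H3K27me3 fragments in the DMSO H3K4me3 libraries were expected to put the peaks near the centres of wide H3K27me3 peaks. The mean distance of 7240 such peaks was 0.563 (0 at the centre, 1 at the edge), above the 0.492 to 0.508 of random placements. The lists give no peak height, so the centre need not hold the most signal. This test therefore cannot decide, and such fragments stay open as a source. Chance dips of the input shared by both DMSO lists are argued against only for part of these peaks. The EPZ6438 H3K27me3 list, called against the other input, overlapped 10.1% of DMSO H3K4me3 peaks, where the highest of the shifted copies reached 0.997%. This share is well below the 48.0%, and shifting breaks any regional clustering that both lists share. For the remaining peaks such dips stay open. Low coverage of the DMSO input over H3K27me3 regions stays open, because no DMSO list was called against the EPZ6438 input, and the overlap of 0.968% in EPZ6438, near the 1.00% of shifted copies, does not bear on it. Whether both marks lie on the same nucleosomes or in different cells was not tested.

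Genes with H3K27me3 in DMSO rose more often, at 11.3% of those that lost the peak. Their low expression is argued against, since the highest of 10000 gene sets matched on mean expression reached 6.32%. Scaling between the arms was expected to end the set test, which passed after median-of-ratios scaling (camera adjusted p = 0.00130, and 0.000314 to 0.117 over its peak settings). Scaling shifts all genes nearly alike and camera compares a set with other genes, so this test cannot decide about scaling. If disappearance of the peak call at the gene end went with the rise, genes that lost it were expected to rise more often than genes that kept it. The odds ratio of lost over kept was 0.516. Lost and kept genes were not matched on expression or on H3K27me3 cover in DMSO, so this ratio cannot decide the question. That ratio was 0.368 at 2.5 kb, 0.392 over whole genes and 0.413 among protein-coding genes, while 25% cover of the window (0.755) and peaks of at least 400 bp (0.712) left it unresolved. The lists give no peak height, so a partial loss of H3K27me3 in peaks that stayed was not tested. The set tests by state passed for 7 sets, against at most 4 in the other splits of the libraries, 1 of 10 splits in all giving as many, and these splits are too few for a share under 0.05.

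The interferon response genes had a median log2 change of -0.87. A single library is argued against, since the highest adjusted p without 1 library was 4.93e-06. Fewer blood cells in the EPZ6438 cultures were expected to lower blood cell markers by about as much. Of 21 such markers 6 had enough reads to test, with a median of 0.17 and an SD of 0.37. None of the 6 passed the limma test, so they say little about blood cells in cultures of a pre-osteoblast line. That the interferon genes vary together between cultures cannot be told apart from an effect of the drug, because 3 samples per arm are few. The estimated correlation was 0.218, above the preset 0.01, and camera adjusted p with it was 0.178. That p cannot decide, because BMP and TGF-beta ligands and antagonists also came to 0.178 with an estimate of -0.0451. An effect of EZH2 inhibition on interferon signalling remains possible and was not tested. The list tests passed for 12 lists, against at most 5 in the other splits, and the gene test for 1001 genes, against at most 2, with 1 of 10 splits giving as many in each case and the splits too few for a share under 0.05.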
